A study of Arabidopsis thaliana with 24 samples.

How the data were processed

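Seeds of the Arabidopsis thaliana wild type Col and of the mutant ref6c were collected at 0, 6, 24 and 48 h of imbibition, with 3 libraries per genotype and time. The labels state that after-ripened seeds germinated on Murashige and Skoog medium in long days, that total RNA was taken with a Takara kit and that libraries were made with a BGISEQ kit. The authors deposited 1 table of TPM values, with 23826 genes and a column for each of the 24 libraries. Each column of deposited TPM values totals 1000000, so values are shares of a library and gene length has been divided out. The submitters' processing notes name fastp 0.20.1, HISAT2 2.1.10, DESeq2 1.26.0 and the genome build TAIR10, without saying what each was used for. The program that counted reads and its strand setting are not stated. Row names carry an Araport11 ending.

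Gene IDs were matched to the gene table of the TAIR10.1 reference, used for symbols, gene spans, product names and neighbours. Of the 23826 IDs 23641 matched, 9712 of them with a symbol, and the 185 others were all mitochondrial or chloroplast genes. TPM multiplied by the reference gene span, introns included, gave whole read numbers, within 0.001 reads, for 99.97% of 462563 values above 0 and in every library for 23636 genes. The recovered depth lay between 16624632 and 19260850 reads per library. Dividing by the whole gene span makes the TPM of genes with long introns small, so TPM values are compared here between groups for the same gene and not between genes.

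The following choices were made before the data were examined: the samples and their groups, the comparisons and tests, the gene lists, the rule for named genes, and the alternatives, except where said otherwise. Genes with a TPM of 1 or more in at least 3 libraries were kept, which left 18481. Values were tested as log2(TPM + 1), with a pseudocount of 1, which understates the change of genes at low TPM. A single fit of 8 group means to the 24 libraries was made in R 4.3.3 with limma 3.58.1, with an intensity trend and 16 residual degrees of freedom. The 13 comparisons were ref6c against Col at each of 4 times, the 3 steps of imbibition within each genotype, and the interaction that tests whether a step differed between genotypes. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 with no fold minimum. Tables were prepared and plotted in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

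Named genes followed a rule. REF6, ELF6 and the 4 CYP707A genes were always taken. Each genotype comparison gave the 10 largest rises and 10 largest falls among called genes that had a symbol, a mean of at least 5 TPM in a group, and the 3 libraries of one genotype all above those of the other. Each Col step and each interaction gave 5 rises and 5 falls, the interaction without the condition on overlap. Each gene list gave up to 4 members with the smallest adjusted p. The text prints those that show each comparison, and a gene picked after its values were seen is marked as such.

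The 24 gene lists and 5 marker lists held 390 entries for 371 loci, written from general knowledge. In 1 case the reference gives the symbol to another locus, and that entry was left out. The reference does not hold 11 listed symbols, 10 entries were given by locus only, and 4 entries are not in the table. The 27 lists with at least 3 members past the filter were tested with camera from limma, at a preset correlation of 0.01 between genes, and again with an estimated correlation, each adjusted over the 27 lists of a comparison. GA inactivation, with 2 members left, and the endosperm markers, with 1, EPR1, were not tested as lists. Of the list calls reported at the preset correlation, only that of the expansins in the 0 to 6 h interaction passed an adjusted p of 0.05 with the estimated one. Genes activated in a step were those called with a log2 change of 1 or more in the step averaged over both genotypes, a contrast that does not use the genotype difference, and their ref6c minus Col difference was tested with camera at the later time. The difference of the step was tested on the same genes after the data were seen. The progress index was compared between genotypes at each time with an exact two-sided permutation test of 3 against 3 libraries.

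The alternatives were a pseudocount of 0.1, no filter, a filter at 5 TPM, median-of-ratios scaling, rescaling without organelle genes and the storage list, fitting only the groups compared, a block for the replicate number, a minimum of 2-fold, no intensity trend, and leaving out each library in turn. For the activated genes a log2 step of 2 and a choice of genes in replicates 1 and 2 with measurement in replicate 3 were added to these. A fit of voom, limma with precision weights, on the recovered reads was chosen after seeing the data. The steps were tested on simulated data with 200 changed genes among 18327: at a true change of 2-fold 84.7% of 59 genes were called, at 1.5-fold 43.4% of 76 and at 4-fold 96.9% of 65, all in the right direction, and 17 of 163 called genes were unchanged. Pairs of replicates differed by 2.08 to 37.2 times the counting error, as chi-square per degree of freedom on recovered reads. Taken over genes together, libraries therefore differed by more than counting error. This was not worked out for genes with few reads, where counting may still limit the precision.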

Results

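Transcript levels were measured by RNA sequencing of Arabidopsis thaliana seeds at 4 times of imbibition, 0, 6, 24 and 48 h, in the wild type Col and in the mutant ref6c. REF6 is a histone demethylase that removes the repressive mark H3K27me3. Each of the 8 groups, 1 per genotype and time, held 3 libraries, 24 in all. Recovered depth lay between 16624632 and 19260850 reads per library. TPM values below are the mean ± SD of the 3 libraries of a group, and log2 differences are given ± SE as ref6c minus Col on log2(TPM + 1), with adjusted p-values from limma. A gene named for the size of its difference between genotypes at a time had, by the naming rule, a symbol, a mean of at least 5 TPM in a group, and all 3 libraries of one genotype above all 3 of the other. For Col steps the condition on overlap was set between the times, and for interactions it was not used. The p-values measure spread between these libraries, since nothing states that the replicates came from separate seed batches, and a growth note speaking of ref6-1;REF6-HA seeds stands with every sample, so the exact seed line rests on the sample names.

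REF6 (AT3G48430) itself was lower in ref6c at every time. In Col it rose from 1.16 ± 0.27 TPM at 0 h to 35.8 ± 3.67 at 6 h and stood at 23.4 ± 2.87 at 24 h and 14.8 ± 1.04 at 48 h. In ref6c the levels were 0.350 ± 0.185, 14.4 ± 0.891, 10.2 ± 1.69 and 8.35 ± 0.701 TPM. The log2 differences were -0.68 ± 0.12 at 0 h (adjusted p = 0.00049), -1.25 ± 0.12 at 6 h (6.5e-08), -1.13 ± 0.12 at 24 h (1.9e-07) and -0.76 ± 0.12 at 48 h (1.6e-05). Every Col library lay above every ref6c library of its time. Values per gene do not tell which part of the transcript remained in the mutant. ELF6 (AT5G04240), a related H3K27 demethylase, differed by -0.23 ± 0.17 at 0 h (0.43), -0.02 ± 0.17 at 6 h (0.98) and 0.25 ± 0.17 at 24 h (0.29), and was higher in ref6c at 48 h by 0.45 ± 0.17 (0.030). That last call ended without Col replicate 1 (0.42, adjusted p = 0.084), Col replicate 2 (0.45, 0.063), ref6c replicate 1 (0.44, 0.070) or ref6c replicate 3 (0.43, 0.078), and without ref6c replicate 1 the difference at 0 h passed the threshold (-0.50, 0.010).

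**Figure D1:**
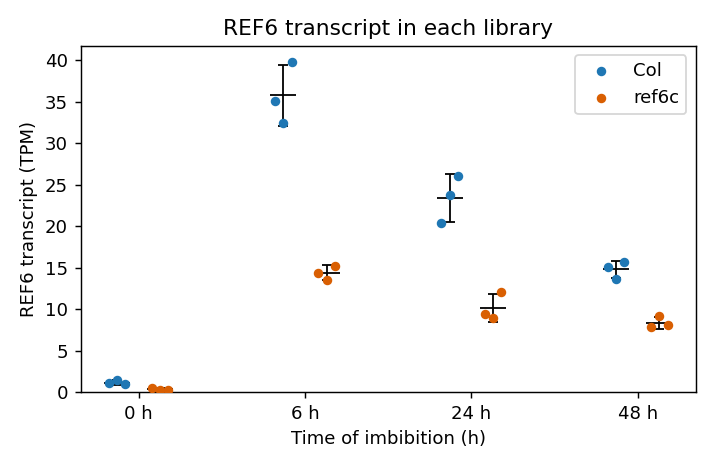
REF6 transcript level in TPM (vertical axis) against hours of imbibition (horizontal axis) for Col and ref6c, with a point per library and the mean ± SD of 3 libraries. At 6 h the Col mean was 35.8 TPM and the ref6c mean 14.4 TPM, and the genotypes did not overlap at any of the 4 times.

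The genotype comparison at each time asked which transcripts differed between ref6c and Col seeds as germination proceeded. Of 18481 genes tested, 2347 differed at 0 h (382 higher and 1965 lower in ref6c), 2959 at 6 h (1089 higher, 1870 lower), 6328 at 24 h (2222 higher, 4106 lower) and 10392 at 48 h (4085 higher, 6307 lower). With a change of at least 2-fold asked for as well, the counts were 256, 393, 858 and 2561, of which 235, 289, 634 and 2248 were lower. Genes whose libraries did not overlap between the genotypes made up 19.8%, 39.2%, 48.0% and 67.6% of those tested, where chance gives 10%.

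**Figure D2:**
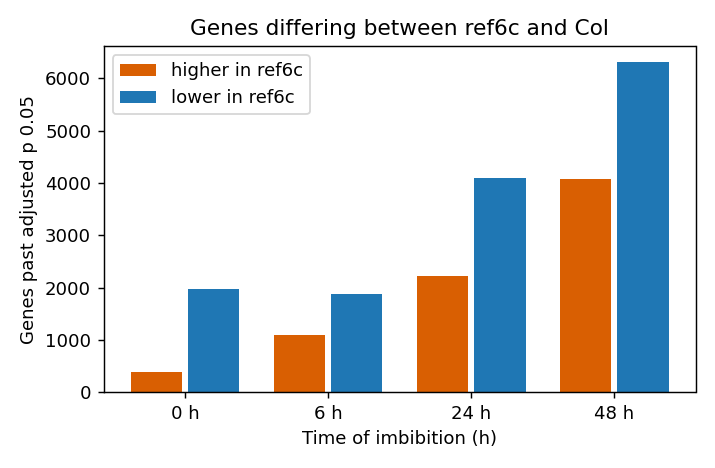
Number of genes (vertical axis) higher or lower in ref6c than in Col at each time of imbibition in hours (horizontal axis), at an adjusted p under 0.05 of 18481 genes tested. Lower genes outnumbered higher ones at each time with the TPM values as deposited, from 1965 against 382 at 0 h to 6307 against 4085 at 48 h, while at 0 h median-of-ratios scaling gave 1558 lower and 1972 higher.

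In dry seeds, at 0 h, the largest differences among genes that met the naming rule were decreases in ref6c. The cytochrome P450 gene CYP71B3 (AT3G26220) stood at 27.2 ± 2.39 TPM in Col and 0.296 ± 0.057 in ref6c (log2 difference -4.44 ± 0.13, adjusted p = 1.5e-16). GSTU13 (AT1G27130), a glutathione S-transferase, stood at 34.1 ± 1.64 TPM in Col and 1.65 ± 0.513 in ref6c (-3.75 ± 0.11, 1.5e-16), and the chloroplast small heat shock protein HSP21 (AT4G27670) at 39.9 ± 2.12 and 2.23 ± 0.511 (-3.68 ± 0.19, 2.7e-12). Other decreases were in the heat shock factor AT-HSFA7B (-3.38), BPC7 (-3.09), CYP81D8 (-3.00), MYB32 (-2.95), GSTF6 (-2.82), the cold-responsive LTI78 (-2.80) and the glucosyltransferase UGT74E2 (-2.73). Increases under the same rule included MIOX2, a myo-inositol oxygenase (AT2G19800, 2.33 ± 0.331 against 7.70 ± 0.327 TPM, 1.39 ± 0.08, 2.1e-11), and the nitrilase gene NIT2 (1.18). FLC, the repressor of flowering, was higher too (AT5G10140, 21.2 ± 0.902 against 36.8 ± 2.87 TPM, 0.77 ± 0.11, 1.7e-05).

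Hormone and light regulators were among the lower genes of dry seeds. Of 6 phytochrome-interacting factors, which act downstream of light perception, 3 were lower and 0 higher (5 lower adjusted over the list alone; camera adjusted p = 0.00532, and adjusted p = 0.207 with an estimated correlation). They were PIF7 (-1.32 ± 0.11, 1.4e-08), PIF4 (-1.14 ± 0.13, 1.7e-06) and PIL5, also named PIF1 (-0.46 ± 0.13, 0.024). The call of PIL5 ended without Col replicate 1 (-0.38, 0.12), Col replicate 2 (-0.44, 0.087), ref6c replicate 2 (-0.23, 0.21) or ref6c replicate 3 (-0.47, 0.060). All 3 tested genes of ABA catabolism, the CYP707A enzymes that inactivate abscisic acid, were lower (3 adjusted over the list alone; camera adjusted p = 0.0319, and adjusted p = 0.207 with an estimated correlation). The differences were -0.61 ± 0.14 for CYP707A1 (0.0035), -0.45 ± 0.14 for CYP707A2 (0.033) and -0.69 ± 0.14 for CYP707A3 (0.0019), which stood at 0.738 ± 0.204 TPM in Col. The CYP707A2 call ended with median-of-ratios scaling (-0.27, 0.22) and without any single library but ref6c replicate 1, with adjusted p between 0.068 and 0.090. CYP707A4, the remaining member of the 4, did not pass the filter at any time. Seed storage genes had 4 of 16 lower and 0 higher (4 adjusted over the list alone; camera adjusted p = 0.598). CRU3 stood at 6006 ± 449 TPM in Col and 3274 ± 809 in ref6c (-0.90 ± 0.19, 0.0026) and SESA1 at -1.01 ± 0.15 (3.6e-05). Hypoxia genes had 2 of 8 higher (2 adjusted over the list alone; camera adjusted p = 0.00532, and adjusted p = 0.439 with an estimated correlation), the first being PCO1, an oxygen-sensing cysteine oxidase (1.09 ± 0.13, 1.2e-06).

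Several further lists passed the set test at 0 h with few members called. Of 9 developmental regulators under Polycomb repression, 1 was higher, FLC (1 adjusted over the list alone; camera adjusted p = 0.0319, and adjusted p = 0.207 with an estimated correlation). Of 33 photosynthesis genes 3 were higher and 1 lower, the same counts adjusted over the list alone. The set test was positive beside a median of -0.05 and a mean of -0.01 (camera adjusted p = 0.0319, and adjusted p = 0.787 with an estimated correlation). PSBR (0.86 ± 0.10, 9.5e-07), a photosystem II subunit, and RBCS1A (0.53 ± 0.09, 0.00025), a Rubisco small subunit, were the clearest. Reserve oil mobilisation had 2 of 21 higher and 2 lower (4 and 2 adjusted over the list alone; camera adjusted p = 0.0477, and adjusted p = 0.787 with an estimated correlation). The set test was positive beside a median of -0.02, which became 0.19, with 9 higher and 1 lower, after median-of-ratios scaling. Of 3 pollen markers, which have no place in a seed, VGD1 (-1.18 ± 0.16, 1.0e-05) and LAT52 (-0.63 ± 0.10, 7.4e-05; 12.4 ± 0.117 TPM in Col) were lower. That made 2 adjusted over the list alone (camera adjusted p = 0.0319, and adjusted p = 0.207 with an estimated correlation). With a pseudocount of 0.1 the LAT52 call ended (-0.69, 0.14). The count at 0 h depended on single libraries: 1393 genes without Col replicate 2, 1268 without ref6c replicate 2, 1446 without ref6c replicate 3 and 6061 without ref6c replicate 1. It was 534 when only the 0 h libraries were fitted, so many 0 h calls rest on the spread and degrees of freedom shared with the other times. Median-of-ratios scaling gave 3530 genes, 1972 higher and 1558 lower.

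At 6 h the largest rise by the naming rule was that of IGMT4 and the largest fall that of AT-HSFA7B. Of 17 tested expansins 5 were lower, and of 10 tested genes of gibberellin synthesis 5 were higher and 2 lower in ref6c. The methyltransferase gene IGMT4 (AT1G21130) stood at 1.02 ± 0.315 TPM in Col and 21.6 ± 2.85 in ref6c (3.49 ± 0.17, 3.2e-13), with IGMT2 (2.84) and IGMT3 (2.47), close copies that modify indole glucosinolates, also higher. SOT16 (AT1G74100), a sulfotransferase of glucosinolate synthesis, stood at 45.1 ± 1.47 TPM in Col and 185 ± 13.7 in ref6c (2.01 ± 0.14, 1.7e-10), and the sulfate-assimilation reductase APR1 at 6.80 ± 0.978 and 27.6 ± 2.17 (1.88 ± 0.12, 6.9e-11). Among decreases, AT-HSFA7B (AT3G63350) stood at 38.6 ± 4.46 TPM in Col and 1.92 ± 0.128 in ref6c (-3.76 ± 0.15, 2.7e-14) and MIOX1 (AT1G14520) at 68.8 ± 4.50 and 4.74 ± 0.319 (-3.60 ± 0.14, 9.7e-15). SAG21 (AT4G02380), a mitochondrial LEA-type protein, was at 323 ± 60.6 and 36.3 ± 5.99 (-3.11 ± 0.19, 2.0e-11). CYP71B19 (-3.18), TOM7-2 (-2.93), MYB32 (-2.75), BLH3 (-2.73) and the MADS-box gene AGL18 (-2.52) were lower as well.

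Of 17 alpha-expansins, proteins that loosen cell walls, 5 were lower and 0 higher at 6 h (6 adjusted over the list alone; camera adjusted p = 0.00137, and adjusted p = 0.133 with an estimated correlation). EXPA2 (-1.92 ± 0.14, 5.1e-10), EXPA1 (-1.80 ± 0.14, 7.8e-10) and EXPA15 (-1.79 ± 0.11, 1.1e-11) led them. Xyloglucan endotransglucosylases and mannanases, which remodel or degrade wall polysaccharides, had 7 of 16 lower (8 adjusted over the list alone; median -0.35; camera adjusted p = 0.00137, and adjusted p = 0.159 with an estimated correlation). TCH4, also named XTH22 (-1.60 ± 0.15, 3.6e-08), and XTH15 (-1.55 ± 0.17, 4.3e-07) were among them. In gibberellin synthesis 5 of 10 genes were higher and 2 lower, the same counts adjusted over the list alone (camera adjusted p = 0.00663, and adjusted p = 0.159 with an estimated correlation). GA3OX2, which makes active gibberellin, stood at 49.1 ± 6.53 TPM in Col and 126 ± 14.1 in ref6c (1.34 ± 0.10, 1.4e-09), and GA3OX1 at 61.6 ± 5.74 and 122 ± 3.71 (0.98 ± 0.16, 8.1e-05).

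Genes named elsewhere as bound by or dependent on REF6 had 7 of 17 lower and 2 higher at 6 h (7 and 2 adjusted over the list alone; camera adjusted p = 0.00854, and adjusted p = 0.159 with an estimated correlation). The auxin exporter PIN7 (-1.76 ± 0.12, 2.0e-10), PIF4 (-1.09 ± 0.13, 2.1e-06) and CYP707A3 (-0.83 ± 0.14, 0.00017) were lower. FLC was higher (1.00 ± 0.11, 2.5e-07) and was 1 of 2 higher genes among 9 Polycomb-repressed regulators (3 adjusted over the list alone; camera adjusted p = 0.00345, and adjusted p = 0.133 with an estimated correlation). Reserve oil mobilisation had 3 of 21 higher and 0 lower (3 adjusted over the list alone; camera adjusted p = 0.00137, and adjusted p = 0.755 with an estimated correlation). Isocitrate lyase, ICL, was at 7307 ± 320 TPM in Col and 10718 ± 129 in ref6c (0.55 ± 0.12, 0.0015). The circadian clock list had 3 of 13 higher, PRR5 first (0.51 ± 0.12, 0.0043), and 0 lower (3 adjusted over the list alone; camera adjusted p = 0.00137, and adjusted p = 0.243 with an estimated correlation). Lists that did not pass the set test included the seed maturation regulators (1 of 9 lower and 1 adjusted over the list alone; camera adjusted p = 0.922) and GA signalling (1 of 9 higher, 3 lower, the same adjusted over the list alone; 0.690). The median of the latter, -0.03, became 0.0043 with median-of-ratios scaling, and its repressor RGL2 was lower (-0.48 ± 0.10, 0.0013).

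At 24 h LEA genes, which protect dry tissues, were higher in ref6c for 20 of 22 members and lower for 0, the same adjusted over the list alone (median 1.39; camera adjusted p = 3.53e-20, and adjusted p = 0.148 with an estimated correlation). EM1 (AT3G51810) stood at 203 ± 48.0 TPM in Col and 713 ± 178 in ref6c (1.81 ± 0.15, 4.2e-09), and GEA6 (AT2G40170), also named EM6, at 196 ± 61.9 and 752 ± 324 (1.91 ± 0.22, 4.2e-07). Storage protein and oil body genes were higher for 9 of 16 and lower for 1 (10 and 2 adjusted over the list alone; median 1.04; camera adjusted p = 2.9e-06, and adjusted p = 0.319 with an estimated correlation). The oleosin OLEO1 stood at 399 ± 82.6 TPM in Col and 1280 ± 584 in ref6c (1.61 ± 0.19, 6.0e-07). Their transcripts took 1.15 ± 0.196% of the total in Col and 2.66 ± 1.11% in ref6c, where replicate 2 stood apart at 3.93% against 2.04% and 2.00%. Without that library 4627 genes differed at 24 h.

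Photosynthesis genes were lower for 24 of 33 and higher for 0 at 24 h (27 adjusted over the list alone; median -0.77; camera adjusted p = 5.71e-08, and adjusted p = 0.319 with an estimated correlation). LHCB5 differed by -2.10 ± 0.22 (1.1e-07). Alpha-expansins were lower for 9 of 17 (9 adjusted over the list alone; median -0.51; camera adjusted p = 0.000333, and adjusted p = 0.148 with an estimated correlation). EXPA1 stood at 946 ± 94.0 TPM in Col and 192 ± 42.0 in ref6c (-2.31 ± 0.14, 9.1e-12). Xyloglucan endotransglucosylases and mannanases were lower for 9 of 16 and higher for 1 (11 and 1 adjusted over the list alone; median -0.99; camera adjusted p = 0.000204, and adjusted p = 0.148 with an estimated correlation). Auxin synthesis and transport had 9 of 13 lower (9 adjusted over the list alone; median -0.58; camera adjusted p = 0.000893, and adjusted p = 0.319 with an estimated correlation). Hypoxia response had 7 of 8 lower (8 adjusted over the list alone; median -0.93; camera adjusted p = 0.00278, and adjusted p = 0.319 with an estimated correlation), and ERF71, also named HRE2, differed by -2.17 ± 0.25 (3.7e-07). DNA replication and cell cycle genes had 12 of 26 lower and 1 higher, the same adjusted over the list alone (median -0.15; camera adjusted p = 0.0194, and adjusted p = 0.474 with an estimated correlation). ABA signalling had 4 of 11 higher and 1 lower, the same adjusted over the list alone (camera adjusted p = 0.00853, and adjusted p = 0.319 with an estimated correlation). ABA synthesis had 3 of 9 higher (3 adjusted over the list alone; camera adjusted p = 0.0281, and adjusted p = 0.319 with an estimated correlation), and the zeaxanthin epoxidase gene ABA1 was higher by 0.97 ± 0.14 (1.2e-05).

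Among single genes at 24 h, QQS (AT3G30720), which affects carbon and nitrogen allocation, was higher in ref6c (0.761 ± 0.235 against 12.5 ± 1.29 TPM, 2.95 ± 0.15, 9.6e-13). TOM7-2 (AT1G64220), an outer mitochondrial membrane translocase subunit, stood at 106 ± 4.03 TPM in Col and 6.12 ± 1.47 in ref6c (-3.93 ± 0.19, 5.5e-13), and SAG21 at 753 ± 74.4 and 66.7 ± 22.1 (-3.53 ± 0.19, 2.0e-12). The zinc finger gene LATE (AT5G48890) was at 23.6 ± 10.4 and 0.663 ± 0.269 (-3.82 ± 0.20, 1.4e-12). The ABA-inactivating genes parted at this time: CYP707A2 (1.28 ± 0.14, 1.5e-07) and CYP707A1 (0.75 ± 0.14, 0.00015) were higher and CYP707A3 (-1.95 ± 0.14, 3.4e-10) lower (the same adjusted over the list alone; camera adjusted p = 0.458). GA3OX2 was now lower (-1.77 ± 0.10, 1.1e-11), as was GA3OX1 (-1.55 ± 0.16, 6.7e-08), in a synthesis list with 2 of 10 higher and 3 lower (the same adjusted over the list alone; median 0.15, mean -0.23; camera adjusted p = 0.983). Of 10 dormancy regulators 3 were higher and 1 lower, the same adjusted over the list alone (camera adjusted p = 0.0738), with RDO5 at 0.78 ± 0.09 (2.4e-07). Polycomb group components had 3 of 12 higher and 4 lower, the same adjusted over the list alone (camera adjusted p = 0.821), the H3K27 methyltransferase gene CLF being lower (-0.71 ± 0.11, 3.0e-05).

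At 48 h all 33 photosynthesis genes were lower in ref6c (33 adjusted over the list alone; median -3.21; camera adjusted p = 1.31e-20, and adjusted p = 0.222 with an estimated correlation). The light-harvesting gene LHCB2.2 (AT2G05070) stood at 179 ± 35.4 TPM in Col and 0.996 ± 1.73 in ref6c (-6.81 ± 0.31, 8.7e-15), and CAB2 (AT1G29920) at 598 ± 141 and 7.0 ± 6.87 (-6.55 ± 0.35, 1.7e-13). The protochlorophyllide reductase PORA (AT5G54190) was at 197 ± 38.3 and 1.98 ± 2.92 (-6.48 ± 0.35, 1.7e-13). The germin-like GER3 (AT5G20630) was at 275 ± 72.0 TPM in Col and 1.16 ± 0.836 in ref6c (-7.03 ± 0.18, 7.1e-19). The vacuolar aquaporin GAMMA-TIP (AT2G36830) was at 288 ± 40.04 and 5.05 ± 6.61 (-6.15 ± 0.40, 6.8e-12). Light-harvesting genes have near-identical copies, so shares between copies depend on how the submitters assigned reads.

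At 48 h storage and oil body genes were higher in ref6c for 15 of 16 (15 adjusted over the list alone; median 1.5; camera adjusted p = 7.55e-09, and adjusted p = 0.261 with an estimated correlation). The cruciferin gene CRU3 (AT4G28520) stood at 483 ± 59.2 TPM in Col and 3409 ± 272 in ref6c (2.82 ± 0.19, 1.3e-11), and CRA1 (AT5G44120) at 2215 ± 231 and 12486 ± 592 (2.50 ± 0.22, 1.4e-09). EPR1_AT2G27380, named with its identifier because AT1G18330 shares the symbol, was the only endosperm marker past the filter. It averaged 8.47 ± 0.230 in Col and 9.93 ± 0.368 in ref6c on the log2 scale (1.45 ± 0.27, 7.2e-05). At 24 h it had differed by 0.26 ± 0.27 (0.49). LEA genes were higher for 20 of 22 and lower for 0 (20 and 1 adjusted over the list alone; median 1.04; camera adjusted p = 7.55e-09, and adjusted p = 0.261 with an estimated correlation). ABA signalling had 8 of 11 higher and 0 lower (8 adjusted over the list alone; median 0.64; camera adjusted p = 0.000753, and adjusted p = 0.261 with an estimated correlation). The phosphatase gene HAI2 (2.01 ± 0.18, 1.1e-09) and the transcription factor ABI5 (0.97 ± 0.16, 1.7e-05) were among the higher ones. CYP707A3 was at 33.5 ± 6.53 TPM in Col and 5.05 ± 0.774 in ref6c (-2.50 ± 0.14, 4.4e-13), CYP707A1 at 33.0 ± 1.81 and 13.9 ± 0.936 (-1.19 ± 0.14, 9.7e-08). CYP707A2 was higher (0.87 ± 0.14, 1.0e-05). Dormancy regulators had 6 of 10 higher and 2 lower, the same adjusted over the list alone (camera adjusted p = 0.0571), with E12A11, also named MFT, at 1.95 ± 0.16 (4.6e-10) and SOM at 1.14 ± 0.12 (3.3e-08).

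At 48 h the DNA replication and cell cycle list had 23 of 26 lower in ref6c and 1 higher, the same adjusted over the list alone (median -0.75; camera adjusted p = 0.000124, and adjusted p = 0.261 with an estimated correlation). PCNA1 stood at 57.2 ± 0.954 TPM in Col and 22.1 ± 2.91 in ref6c (-1.34 ± 0.12, 8.2e-10). The cyclin CYCD2;1 was the higher member (0.63 ± 0.06, 1.4e-09). Auxin synthesis and transport had 11 of 13 lower (11 adjusted over the list alone; median -0.94; camera adjusted p = 0.00103, and adjusted p = 0.261 with an estimated correlation). The importer LAX3 was lowest relative to Col (-2.49 ± 0.08, 4.6e-17). Root and root hair markers had 6 of 9 lower (6 adjusted over the list alone; median -0.41; camera adjusted p = 0.00769, and adjusted p = 0.261 with an estimated correlation). LRX1 was at 22.3 ± 8.02 TPM in Col and 0.306 ± 0.530 in ref6c (-4.16 ± 0.21, 5.5e-14). Xyloglucan endotransglucosylases and mannanases had 10 of 16 lower and 2 higher, the same adjusted over the list alone (median -1.04; camera adjusted p = 0.0267, and adjusted p = 0.261 with an estimated correlation). Alpha-expansins had 9 of 17 lower and 5 higher, the same adjusted over the list alone (camera adjusted p = 0.0571), EXPA7 (-3.94 ± 0.14, 7.7e-17) and EXPA18 (-3.69 ± 0.12, 2.2e-17), both of root hairs, being lowest. The clock list had 9 of 13 higher and 1 lower, the same adjusted over the list alone (median 0.33; camera adjusted p = 0.00603, and adjusted p = 0.261 with an estimated correlation).

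Other lists did not pass the set test at 48 h. Genes named elsewhere as REF6-bound or REF6-dependent had 12 of 17 lower and 3 higher, the same adjusted over the list alone (median -0.97; camera adjusted p = 0.0692). The lipoxygenase LOX1 stood at 202 ± 40.8 TPM in Col and 11.9 ± 2.45 in ref6c (-3.97 ± 0.16, 6.5e-16). Heat shock proteins had 8 of 11 lower (8 adjusted over the list alone; 0.0624), and leaf epidermis and guard cell markers 5 of 8 lower (5 adjusted over the list alone; 0.0793). The stomatal factor SPCH was among the latter (-0.99 ± 0.11, 3.9e-08). Seed coat markers had 2 of 3 lower (2 adjusted over the list alone; 0.458), pollen markers 1 of 3 (1 adjusted over the list alone; 0.298). The H3K27 demethylase family list had 2 of 5 higher and 1 lower, the same adjusted over the list alone (0.710), its median of -0.20 lying beside a mean of 0.10. JMJD5, also named JMJ30, was higher by 1.29 ± 0.14 (4.2e-08). GA synthesis had 4 of 10 higher and 4 lower, the same adjusted over the list alone (0.691; median 0.05, mean -0.31). GA3OX1 stood at 20.7 ± 4.47 TPM in Col and 0.736 ± 0.294 in ref6c (-3.64 ± 0.16, 3.4e-15). FLC stood at 7.83 ± 1.46 TPM in Col and 25.6 ± 0.347 in ref6c (1.60 ± 0.11, 8.1e-12), and the defence gene PR1 (AT2G14610) at 0.678 ± 0.065 and 28.7 ± 11.8 (4.07 ± 0.17, 2.9e-15).

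**Figure D3:**
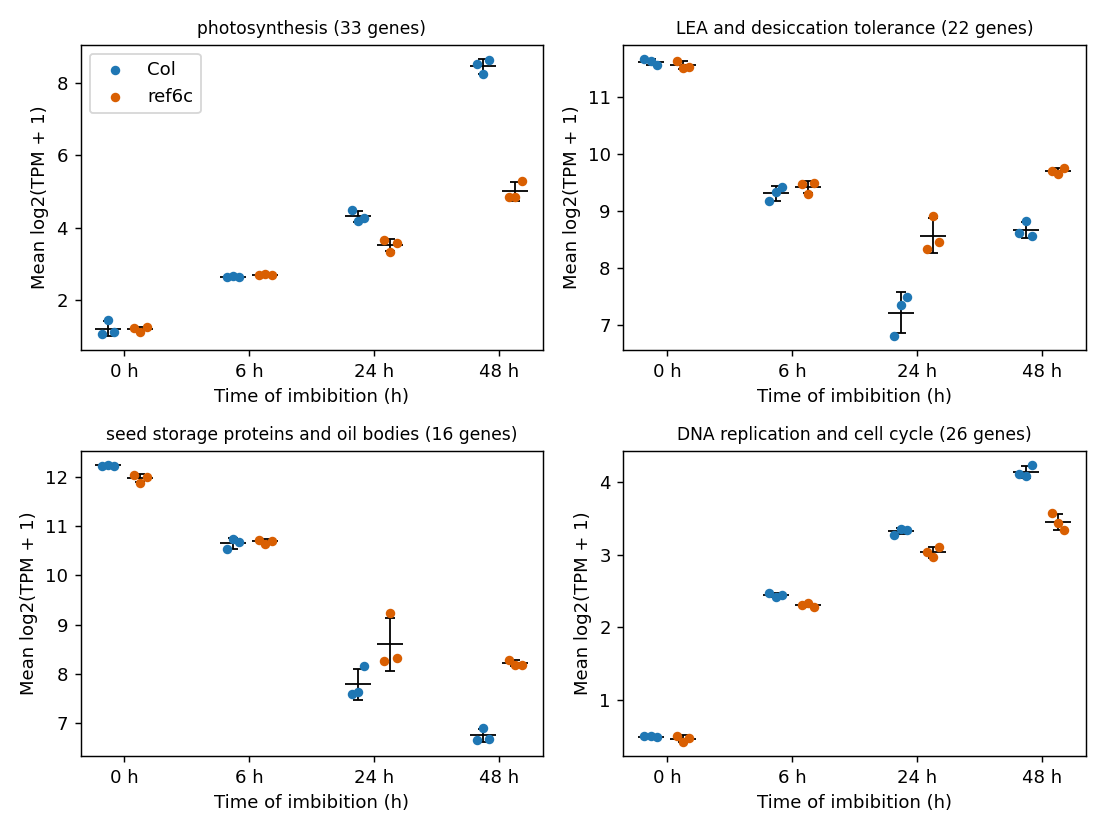
Mean log2(TPM + 1) over the members of 4 gene lists (vertical axes) against hours of imbibition (horizontal axes) in Col and ref6c, with a point per library and the mean ± SD of 3 libraries. Photosynthesis genes averaged 8.47 in Col and 5.01 in ref6c at 48 h, while storage and oil body genes averaged 6.75 in Col and 8.22 in ref6c.

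The steps of imbibition in Col give the course against which the mutant was compared. From 0 to 6 h 15648 genes changed, 13856 of them upwards. The median of all genes moved by 1.24 on the log2 scale, while the share of storage transcripts dropped from 21.1 ± 0.519% to 6.94 ± 0.481% and that of LEA transcripts from 15.8 ± 0.102% to 2.95 ± 0.231%. Median-of-ratios scaling shifted that median by -1.22 and gave 7501 rises and 6901 falls among 14402 genes. TSO2, a ribonucleotide reductase subunit, rose by 8.71 ± 0.08 (1.4e-27) and the nucleolar fibrillarin FIB2 by 7.38 ± 0.09 (1.9e-25), far beyond that shift, and the galactinol synthase GolS2 changed by -6.10 ± 0.20 (2.1e-18). All 21 reserve oil mobilisation genes rose as deposited (21 adjusted over the list alone; median 1.88; camera adjusted p = 0.0605), while median-of-ratios scaling gave 9 rises and 6 falls (median 0.08). Heat shock proteins fell for 8 of 11 and rose for 0 (8 adjusted over the list alone; median -1.85; camera adjusted p = 7.12e-10, and adjusted p = 0.105 with an estimated correlation).

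From 6 to 24 h 13540 genes changed in Col, 7031 upwards and 6509 downwards. XTH31 (9.05 ± 0.10, 8.5e-26), EXPA2 (7.49 ± 0.14, 8.4e-22) and EXPA9 (7.08 ± 0.13, 7.1e-22) were among the rises. In the expansin list 13 of 17 rose and 0 fell (13 adjusted over the list alone; camera adjusted p = 3.17e-05, and adjusted p = 0.1002 with an estimated correlation). All 16 storage and oil body genes fell (16 adjusted over the list alone; median -3.17; camera adjusted p = 8.96e-08, and adjusted p = 0.296 with an estimated correlation). From 24 to 48 h 11776 genes changed, 6553 upwards and 5223 downwards. All 33 photosynthesis genes rose (33 adjusted over the list alone; median 4.16; camera adjusted p = 1.53e-19, and adjusted p = 0.154 with an estimated correlation). The aquaporin TIP2 went from 0.260 ± 0.255 to 691 ± 119 TPM (9.11 ± 0.25, 1.1e-18). LEA genes rose again for 19 of 22 members and fell for 1 (19 and 2 adjusted over the list alone; median 1.45; camera adjusted p = 4.63e-05, and adjusted p = 0.625 with an estimated correlation). In ref6c the 3 steps changed 15607, 12498 and 10104 genes, and median-of-ratios scaling gave 14376 for the first, 7331 up and 7045 down, with a shift of -1.29 in the median of all genes.

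Whether a step itself differed between the genotypes was tested by the interaction, with values given as the ref6c step minus the Col step. From 0 to 6 h 1487 genes differed (952 higher, 535 lower), among them IGMT4 (4.92 ± 0.24, 9.7e-12), which went from 0.487 ± 0.149 TPM at 0 h to 21.6 ± 2.85 at 6 h in ref6c, and EXPA2 (-2.13 ± 0.20, 1.2e-07). Alpha-expansins had 5 of 17 lower in this test (5 adjusted over the list alone; camera adjusted p = 6e-06, and adjusted p = 0.0359 with an estimated correlation). The count was 3637 without ref6c 0 h replicate 1, 959 with voom on recovered reads, and split into 732 higher and 832 lower of 1564 with median-of-ratios scaling. From 6 to 24 h 2917 genes differed (1100 higher, 1817 lower). LEA genes were higher for 20 of 22 (21 adjusted over the list alone; median 1.28; camera adjusted p = 1.37e-18, and adjusted p = 0.406 with an estimated correlation), and GA3OX2 differed by -3.11 ± 0.15 (8.3e-12). With a pseudocount of 0.1 this count was 1910. From 24 to 48 h 4059 genes differed (1068 higher, 2991 lower). Of 33 photosynthesis genes 31 were lower (32 adjusted over the list alone; median -2.10; camera adjusted p = 1.41e-27, and adjusted p = 0.0811 with an estimated correlation). The step of EXPA1, which was lower in ref6c at 24 h, was higher (2.55 ± 0.19, 2.5e-10).

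To see how genes that rise during imbibition differed between the genotypes, genes were taken that rose by at least 1 on the log2 scale in a step averaged over both genotypes, and their genotype difference was read at the later time. The 10626 genes activated from 0 to 6 h had a median difference of -0.08 at 6 h (camera p = 3.386e-05, and p = 0.322 with an estimated correlation), with 462 higher and 1358 lower in ref6c. In that step the median of all genes rose by 1.24 in Col and 1.29 in ref6c, more than the threshold of 1. This first set is therefore not limited to genes that rose relative to the others. The 2660 genes activated from 6 to 24 h had a median of -0.33 at 24 h (1.021e-19, and p = 0.0134 with an estimated correlation), with 135 higher and 1412 lower. The 1676 genes activated from 24 to 48 h had a median of -1.53 at 48 h (3.16e-48, and p = 0.00088 with an estimated correlation), with 119 higher and 1413 lower. With a step of at least 2 on the log2 scale the medians at 24 and 48 h were -0.51 and -2.67. A difference at the later time includes any already present before the step, so the ref6c step minus the Col step was read for the same genes, a test added after the data were seen. From 0 to 6 h its median was 0.061, after a median difference of -0.13 at 0 h, so weaker activation was not shown in that step (p = 0.608, and p = 0.901 with an estimated correlation). From 6 to 24 h it was -0.23 (8.228e-14, and p = 0.0363 with an estimated correlation) and from 24 to 48 h -1.14 (4.989e-81, and p = 6.687e-05 with an estimated correlation), with 797 and 1201 genes rising less in ref6c and 140 and 33 more. Genes that fell in the same steps had medians at the later time of 0.12, 0.20 and -0.03. Of these, 138, 544 and 129 were higher in ref6c and 43, 163 and 144 lower. Camera gave p = 2.376e-08, 8.062e-15 and 0.0767 at the preset correlation, and p = 0.0630, 0.0425 and 0.558 with an estimated one. As a difference of the step their medians were 0.21, 0.18 and 0.19. The step was higher in ref6c for 124, 339 and 109 genes and lower for 11, 128 and 21. Camera gave p = 3.801e-06, 3.232e-07 and 2.457e-09 at the preset correlation, and p = 0.118, 0.167 and 0.0606 with an estimated one. The median of 0.19 followed a median difference of -0.18 at 24 h.

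An index per library, the mean of the 2660 rising genes minus that of the 1509 falling genes of the 6 to 24 h step, placed each library along imbibition. Col stood at -3.53 ± 0.036, -2.52 ± 0.053, 1.32 ± 0.150 and 1.59 ± 0.034 at the 4 times and ref6c at -3.34 ± 0.101, -2.70 ± 0.039, 0.627 ± 0.216 and 0.915 ± 0.047. The differences of 0.19, -0.18, -0.69 and -0.67 each separated the 3 libraries of one genotype from the 3 of the other, with p = 0.1 in the exact two-sided permutation test, the smallest value that 3 against 3 can give. With genes of the 0 to 48 h change instead, the difference at 0 h was 0.04 (exact permutation p = 0.4), and at 24 h it was -0.46.

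**Figure D4:**
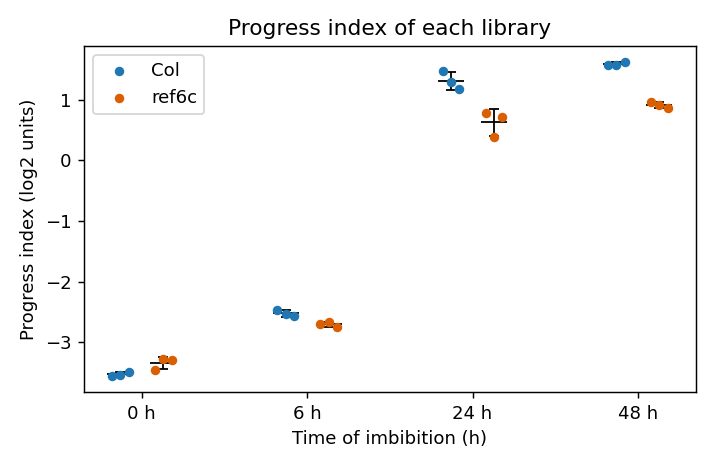
Index of progress through imbibition in log2 units (vertical axis) against hours of imbibition (horizontal axis) for Col and ref6c, with a point per library and the mean ± SD of 3 libraries. The ref6c mean lay above Col at 0 h by 0.19 and below it at 24 h, where it was 0.627 against 1.32, and at 48 h, where it was 0.915 against 1.59.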

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

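The 48 h tests on genes changed at least 2-fold, the 24 h tests without a library and after rescaling, and the 0 h tests of scaling were chosen only after the result was seen. For 1487 genes the change from 0 to 6 h differed between ref6c and Col by the interaction test. The largest by the naming rule were IGMT4 (4.92), IGMT2 (3.46), the glutathione S-transferase GSTU12 (3.46), HSP21 (2.87), the ABC transporter PEN3 (AT1G59870, 2.84), CYP71B19 (-2.73), CYP71B2 (-2.63), SBP3 (-2.17), BLH3 (-2.13) and EXPA2 (-2.13). These are log2 values of the ref6c step minus the Col step. With voom on recovered reads, an alternative added after the data were seen, the calls ended for HSP21 (2.24, adjusted p = 0.0799), CYP71B19 (-1.17, 0.449), CYP71B2 (-1.44, 0.322), SBP3 (-1.68, 0.0877) and BLH3 (-1.08, 0.160). The HSP21 call also ended with a pseudocount of 0.1 (2.35, 0.0893). The change from 6 to 24 h differed for 2917 genes, led under the same rule by RTFL10 (2.36), GEA6 (1.98), CYP71B4 (1.84), GLYI8 (1.82) and EXPA2 (1.78) and by LATE (-3.82), DIN10 (-3.56), the early light-induced protein ELIP1 (-3.52), IGMT4 (-3.47) and GA3OX2 (-3.11). The CYP71B4 call ended with voom (0.37, 0.787). From 24 to 48 h 4059 genes differed, led under that rule by ATSDI1 (3.24), PR1 (3.12), EXPA1 (2.55), the ubiquitin ligase PUB19 (2.42) and BGLU28 (2.41) and by GER3 (-6.94), LHCB2.2 (-6.61), PORA (-6.33), the cell wall protein PRP3 (-6.01) and the arabinogalactan protein AGP3 (-5.91).

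Other assignments of the libraries to genotypes were fitted for each count. For the interactions, 100 assignments within the times were used, the real one included. From 0 to 6 h 7 of them gave at least as many genes as the real 1487, the highest other giving 3998, so chance was not excluded, and 5 of these mixed the genotypes at both times. From 6 to 24 h it was 9 against the real 2917, with 6737 as the highest other, and from 24 to 48 h 9 against 4059, with 11175, so chance was not excluded by the share there either. All 9 in each of these steps kept the genotypes whole at 1 time or more. Such assignments keep a real genotype difference in the contrast, so the share decides little there. Those that mixed the genotypes at both times called at most 2 and 3 genes. For the comparisons of 3 with 3 libraries the 10 splits are too few for a share under 0.05. The real value was matched by 1 of 10 splits, itself, for the genotype comparisons at 6 h (2959, highest other 2), 24 h (6328, highest other 6) and 48 h (10392, highest other 1). It was likewise 1 for the Col steps (15648, 13540 and 11776, highest others 0, 4 and 3) and for the ref6c steps (15607, 12498 and 10104, highest others 0, 1 and 1). It was 1 as well for the medians of activated genes (-0.08, -0.33 and -1.53, highest others 0.04, 0.18 and 0.64 in size). At 0 h 2 of the 10 splits gave at least 2347 genes, and the other, Col replicates 1 and 2 with ref6c replicate 1 against the rest, gave 4542, which points to a structure of the dry seed samples beside genotype.

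At 24 h 6328 genes differed, and a candidate explanation is that ref6c seeds trail Col along imbibition. Across genes the difference at 24 h had a Pearson r of -0.40 with the Col change from 6 to 48 h, which shares no library with it, though genes are not independent replicates. Weaker changes in ref6c without a delay would also give a negative r, so it cannot tell these apart. Leaving out ref6c replicate 2, which stood apart, gave 4627 genes, and rescaling without storage and organelle transcripts gave 6057, so neither that library nor that share accounts for most of the count. A first test at 48 h asked whether ref6c levels lay between those of Col at 24 and 48 h. This held for 44.16% of 2561 genes changed at least 2-fold, 9.585% of the higher and 48.98% of the lower. It cannot decide, since the place of ref6c at 48 h along the Col course is not settled. Its progress index (0.915) lay below that of Col at 24 h (1.32), but weaker changes without a delay would lower the index too. List means went both ways. Photosynthesis genes averaged 5.01 in ref6c at 48 h, past the 4.32 of Col at 24 h towards its 8.47 at 48 h. Storage and oil body genes averaged 8.22, short of the 7.79 to which Col had fallen at 24 h. At 48 h a trail and other effects of the mutation cannot be told apart: against the range of all 4 Col times 72.52% of the 313 higher genes lay within and 86 outside, between what each predicts, and of the 2248 lower ones 91.33% lay within but 81.0% had a Col time under 1 TPM, where the floor keeps them inside (23.3% of the higher ones had such a time).

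In dry seeds lower genes outnumbered higher ones, 1965 against 382. Rescaling without storage and organelle transcripts left 9.73% of called genes higher, which argues against the share of those transcripts. The Pearson r across genes between the difference and log2 gene span was -0.0855, so the difference varied little with gene span. The span includes introns, so a bias with transcript length, as from RNA breakdown, was not tested by it. An exchange of ref6c replicate 1 and Col replicate 3 is argued against by 106 genes called in the same direction, with a log2 difference of at least 1, at the 3 later times, on which ref6c replicate 1 scored 0.523 and Col replicate 3 scored -0.53, a difference of 1.051. After median-of-ratios scaling 55.86% of called genes were higher, but that scaling centres the differences by its construction, so a uniform shift of the TPM scale and an excess of lower genes cannot be told apart. A difference in the seeds of the mutant stays open and was not tested.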

How the results depend on the processing

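The voom fit on recovered reads and the difference of the step for activated genes were chosen only after the result was seen. Among the 538 named-gene results no called gene changed sign under the alternatives run for it, and the signs of other called genes are not given here. The excess of lower genes at 0 h and some list medians did change sign under median-of-ratios scaling. Counts called by voom stayed within 1.5 times the reported ones (2471, 2940, 6295 and 10244 for the genotype comparisons), except 959 for the 0 to 6 h interaction. Other counts moved by more than that for the 6 to 24 h interaction with a pseudocount of 0.1 (1910), and for the 0 h comparison with median-of-ratios scaling (3530) and with only its own libraries fitted (534). The cause was not tested, though the last fit has fewer libraries and uses the spread at 0 h alone. At 0 h ref6c replicate 1 differed from replicates 2 and 3 by 37.2 and 22.9 times the counting error. Pairs of replicates at the later times differed by 2.08 to 19.5 times. The spread shared over 8 groups may therefore understate that at 0 h. No filter, a filter at 5 TPM, rescaling without organelle and storage genes, and no trend kept all counts within 1.5 times. A minimum of 2-fold lowered counts by its construction, to 256, 393, 858 and 2561 for the genotype comparisons in order of time, 4718 and 3266 for the later Col steps, 3768 and 1355 for those of ref6c, and 322, 723 and 1633 for the interactions. Whether the numbers of the replicates pair the libraries was not settled: 7 of 12 same-numbered pairs correlated at r above 0.1 (-0.12 to 0.48), and 7 of 12 Col libraries matched their own number best. With the replicate number as a block the 0 h count was 2384.

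Leaving out a library gave 1268 (without ref6c replicate 2) to 6061 (without ref6c replicate 1) genes at 0 h, with 1393 without Col replicate 2 and 1446 without ref6c replicate 3. The 0 to 6 h interaction ranged from 1141 to 3637, the highest again without ref6c replicate 1 of 0 h. Ranges for the rest stayed within 1.5 times: 2124 to 2450 at 6 h, 4627 to 5940 at 24 h, 9257 to 9851 at 48 h, 2224 to 2947 and 3472 to 4111 for the later interactions. The median of genes activated from 0 to 6 h, -0.0793, was past the threshold at the preset correlation and not with an estimated one (p = 0.322), was -0.12 with genes chosen in replicates 1 and 2 and measured in replicate 3, and changed sign as a difference of the step (0.0613). The later medians ranged from -0.51 with a step of log2 2 to -0.23 as a difference of the step, and likewise from -2.67 to -1.14. With genes of the 0 to 48 h change the progress index differed by 0.0381 at 0 h, -0.46 at 24 h and -0.58 at 48 h; the cause was not tested.

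Of 108 list results in the genotype comparisons, called or not, 33 lost their call with an estimated correlation and 1 with the block. Those 33 include every list call reported above for the genotype comparisons, so none of these held with an estimated correlation. Of 538 named-gene results, calls ended in 46 when some library was left out, in 19 with median-of-ratios scaling, in 21 with a pseudocount of 0.1, in 2 with the block and in 18 with voom. Calls were gained, in the same order, in 33, 22, 18, 5 and 13. With median-of-ratios scaling the sign of the median changed for DNA replication, GA signalling, leaf epidermis and seed coat markers, Polycomb group components, oil mobilisation and seed maturation at 0 h. It changed as well for GA signalling and phytochrome-interacting factors at 6 h, for Polycomb group components at 48 h, and for photosynthesis in Col from 0 to 6 h. In simulated data, where depth was not varied and noise was independent between genes, 50 of 59 genes with a 2-fold change were called. Of those with a mean of 5 TPM or more it was 39 of 39. At 1.5-fold these were 33 of 76 and 27 of 50.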

Other observations

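The genes named in this part and the grouping of genes into families by product name were chosen only after the genotype differences were seen, while the tests were set before their own results were. Beside the genes described for single times, 284 genes were lower and 46 higher in ref6c at all 4 times. MIOX1, a myo-inositol oxygenase, was lower by log2 differences of -2.65, -3.60, -3.13 and -3.51 at 0, 6, 24 and 48 h. Its Col levels lay between 29.2 ± 1.65 and 68.8 ± 4.50 TPM and its ref6c levels between 2.97 ± 0.534 and 5.89 ± 1.23. MYB32, a transcription factor, differed by -2.95, -2.75, -3.13 and -2.92, and the heat shock factor HSFA7A by -1.75, -2.14, -3.20 and -3.21. The aquaporin PIP2A differed by -1.19, -1.58, -2.92 and -3.23, and the locus AT3G60980, which has no symbol, by -2.01, -4.30, -4.23 and -3.73. Among the higher genes, the locus AT3G44006 differed by 4.76, 3.99, 5.03 and 5.99, QQS by 1.00, 2.09, 2.95 and 3.79, and FLC by 0.77, 1.00, 1.39 and 1.60. FLC stood at 21.2 ± 0.902 TPM at 0 h and 7.83 ± 1.46 at 48 h in Col, and at 36.8 ± 2.87 and 25.6 ± 0.347 in ref6c.

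Grouped by product name, 35 of 41 peroxidases were lower and 1 higher in ref6c at 48 h (median -1.70; camera adjusted p = 7.206e-14, and adjusted p = 0.2955 with an estimated correlation). So were 34 of 42 arabinogalactan proteins, with 1 higher (-1.05; the same 2 values 4.552e-08 and 0.3105), and 29 of 41 core histones, with 5 higher (-0.69; 0.000386 and 0.790). Of 33 glutathione S-transferases 22 were lower and 3 higher (-0.73; 0.000386 and 0.3105), and of 42 WRKY factors 25 were lower and 6 higher (-0.58; 0.00492 and 0.790). Pentatricopeptide repeat proteins, which act on organelle RNA, went the other way at 48 h, with 69 of 254 higher and 16 lower (median 0.14, camera adjusted p = 0.000295, and adjusted p = 0.995 with an estimated correlation). Earlier they were lower, with 33 lower and 1 higher at 0 h (median -0.17, the same 2 values 0.0353 and 0.995). At 6 h 16 were lower and 1 higher (median -0.10, with 0.160 and 0.995). Ribosomal proteins were lower at 6 h for 114 of 309 and higher for 4 (-0.20; 2.455e-13 and 0.790). At 0 h 102 were lower and 5 higher (-0.18, with 5.656e-07 and 0.995), a median that became 0.00082 with median-of-ratios scaling. Later the ribosomal proteins did not pass, with 56 lower and 19 higher at 24 h (-0.09, with 0.442 and 0.995). At 48 h 62 of them were lower and 59 higher (0.03, with 0.154 and 0.995). Of 64 tests, 16 families at 4 times, 16 passed with the preset correlation and 0 with an estimated one, where 4 had an unadjusted p under 0.05 and the smallest adjusted p was 0.2955, so a shared move of family members beyond their own correlation was not shown.

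The 284 genes lower at all 4 times were 18.84 times the 15.08 expected from independent lists of the same sizes, which is consistent with a set of genes that stayed low in the mutant through imbibition. Of the 401 genes called at all 4 times in any direction 82.3% had 1 direction throughout, against 39.96% if directions were independent. Genes that are merely easy to call do not account for this shared direction. They can account for part of the 18.84-fold excess, since all 4 comparisons share 1 variance per gene. After median-of-ratios scaling 80.63% of the 284 (229) were still called lower at all 4 times, which argues against the scale of the TPM values. The fullest window of 500 neighbouring tested genes held 5.634% of them (16), against a median of 16 and a 95th percentile of 19 in 1000 random sets, which argues against a single chromosome segment of another background. Scattered differences between the lines of seeds were not tested. A direct effect of REF6 on these genes stays open, since H3K27me3 was not measured in these libraries.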
